A study of Mus musculus with 31 samples.

How the data were processed

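The series holds RNA sequencing of 31 single sensory neurons of dorsal root ganglia, the clusters of touch and pain neurons beside the spinal cord, from male C57BL/6J mice. Per the labels' protocols, neurons were dissociated with collagenase and papain, cultured for 24 h with nerve growth factor, GDNF, BDNF, NT-3 and NT-4, and recorded in whole-cell patch clamp while a blunt glass probe indented the cell body. The labels give each cell's age in days, its action potential type (nociceptor or mechanoreceptor), its sequencing batch and the amplitude in nA of its rapidly adapting mechanically activated current, or state that there was none. The cytosol was then drawn into the pipette and made into cDNA with a SMART kit for low RNA input and into libraries with a Nextera kit, which were read from one end at 50 bases. This chemistry does not mark the strand, so that reads of overlapping genes on opposite strands cannot be told apart. According to the labels, the action potential categories given match the RNA profile of common marker genes, so that marker genes are not independent evidence of a difference between the categories.

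The authors deposited 4 tables: a table of raw counts per Ensembl gene and a table of TPM (length-scaled transcript abundances) for each of 2 sequencing batches. Per the submitters' processing notes, the genome build was mm10, and the tools were bcl2fastq 2.17.1.14, FastQC 0.11.5, STAR 2.5.2a, R 3.6.1 and edgeR 3.22.5, with no role or order stated. The read counter and the annotation release were not stated. The deposited counts were whole numbers whose column totals differed between cells, and the columns of the deposited TPM values shared a single total. The count table of batch 1 had 22332 genes for 7 cells and that of batch 2 had 20711 genes for 24 cells, and 0 columns of values were left without a sample. Genes with no name (87 in batch 1 and 85 in batch 2) were left out. Of the remaining genes, 17507 were in both tables. Of the named genes of batch 2, 20610 were found in GENCODE vM21, a mouse annotation on the same build, and 97.6% of them had the same start and end there. Exon lengths were taken from that annotation. Columns of the same group were checked for copies of the same library. The lowest chi-square per degree of freedom between 2 columns of a group was 10.2, so that no column was a resampling of another of its group. Columns of different groups were not checked in this way.

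Total counts per cell ranged from 7030197 to 67010440 in batch 1 and from 248760 to 4764250 in batch 2. Reads carried no molecular identifiers, so that intervals and floors cover counting error only.

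The labels name no animal. An animal is dissected at 1 age, so cells that differ in age came from different animals, while cells of the same group and age may share an animal. Counts were therefore summed over the cells of a group that had the same age, and these age pools were the replicates. This gave 5 pools from 7 adult nociceptors without current (nonresponders), 5 pools from 9 adult nociceptors with current (responders), 3 pools from 7 adult mechanoreceptors with current and 4 pools from 8 juvenile nociceptors with current. Pools of different groups with the same age may also share an animal, which no label could settle.

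Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood fits and Benjamini-Hochberg adjusted p under 0.05. Adult mechanoreceptors against adult nociceptors, and adult against juvenile nociceptors, were tested in 1 fit over the 12 pools of batch 2. Responder against nonresponder nociceptors were tested over their 10 pools, with genes present in both tables. All nonresponders were in batch 1 and all responders in batch 2, so that batch and group cannot be told apart. Expression values are TMM-scaled CPM (counts scaled to a common library total) per pool, as mean ± SD over pools, and fold changes are edgeR's log2 estimates with their standard error (SE). A standard error was obtained as the estimate divided by the square root of the F statistic.

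Before the data were examined, 28 gene lists were fixed (sensory neuron markers, ion channels, receptors, mechanotransduction, cytoskeleton, metabolism, stress and injury responses, synapse, and markers of other cell types), of which the 26 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists of a comparison. Camera with the correlation estimated from the data and fry were run beside it. The rule for the genes named was also fixed beforehand: the genes with the smallest adjusted p among those past the threshold, up to 4 members past the threshold (or the 2 with the smallest p) of each list described, and in every case Piezo2, Scn10a, Nefh, Ntrk1, Ntrk2 and Ntrk3. After the data were seen, the threshold for list members was read as an adjusted p under 0.05 adjusted over the list alone, and the lists to describe were chosen. Currents were compared on the log10 scale as means over cells per pool, with exact permutation tests, two-sided. Correlations of current with expression used the 9 nociceptor pools of batch 2, the mean log2(CPM+1) over the cells of a pool and exact permutation tests. These were run in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. Figures were drawn with matplotlib 3.10.9.

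Alternatives fixed before the data were examined were median-of-ratios size factors, library size alone, DESeq2 1.42.0, no filter and a minimum count of 50, a fit without the robust option, limma on the mean log2(CPM+1) per pool, limma-voom on single cells with the correlation within ages estimated, the same with the replicate numbers of the labels as a block, merging of consecutive ages, fits of the compared groups alone, leaving out each pool, a filter on cells with under 100000 counts or 2000 genes, a glial marker covariate, and limma on log2(TPM+1) or log2(TPM+0.1) with or without a minimum mean TPM of 1. Chosen after seeing the data were the removal of cells with over 18000 genes detected, the removal of the mechanoreceptor with the highest current, the removal of each pool's trend with exon length (a loess curve with span 0.5), and the thinning of the pools of the response comparison to 637157 counts each. Genes detected per cell were also counted after thinning each cell to 200000 counts. Medians of the lists under TMM, median-of-ratios, library size and log2(TPM+1) scaling, also relative to the median of all genes, were likewise computed after seeing the data.

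The code was tested on simulated data with 200 genes changed 2-, 8- or 32-fold among the real genes. In the simulated comparison of mechanoreceptors with nociceptors (14066 genes), edgeR recovered 0% of genes raised 2-fold, 50.0% of those raised 8-fold and 75.8% of those raised 32-fold, and 0%, 27.3% and 48.5% of those lowered as much. For adult against juvenile nociceptors (14066 genes) it recovered 0%, 58.8% and 66.7% of raised genes and 0%, 30.3% and 51.5% of lowered genes. For responders against nonresponders (12421 genes) these shares were 0%, 61.8% and 60.6%, and 2.94%, 54.5% and 75.8%. Unchanged genes made up 1 of 68, 4 of 73 and 2 of 87 of edgeR's calls, and 25.8%, 21.7% and 23.6% of DESeq2's calls. A list of genes raised 4-fold passed camera in each of the 3 simulations, and 0, 1 and 0 of the unchanged lists did. Genes were simulated independently of each other, while real oxidative phosphorylation genes had an estimated correlation of 0.60 in responders against nonresponders. The simulations therefore cannot show how often camera calls unchanged lists of correlated genes. Limma-voom on cells failed the first simulation, in which cells of a pool shared their variation: 4395 of 4522, 56 of 124 and 3073 of 3214 calls were then unchanged genes. After that failure a second simulation was written in which each cell varied on its own, and 2 of 78, 4 of 88 and 0 of 92 calls were unchanged genes. The fit on cells therefore limits false calls only if cells of the same age vary independently. The correlation it estimated within ages was -0.004 in batch 2 and 0.026 for responders and nonresponders.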

Results

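Expression was measured in 31 single neurons of mouse dorsal root ganglia, each recorded in patch clamp before its RNA was collected. The cells fell into 4 groups: 7 adult nociceptors without a mechanically activated current (nonresponders), 9 adult nociceptors with a rapidly adapting current (responders), 7 adult mechanoreceptors with such a current and 8 juvenile nociceptors with such a current. Adult cells came from mice of 84 to 115 days and juvenile cells from mice of 26 to 31 days. Cells of the same group and age were summed into pools, which gave 5, 5, 3 and 4 replicates.

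Depth differed between the sequencing batches. The nonresponders, which alone formed batch 1, had 7030197 to 67010440 counts per cell (median 34219589) and 12434 to 20195 genes detected. The 24 cells of batch 2 had 248760 to 4764250 counts (median 1169662.5) and 9069 to 19780 genes. Within batch 2 the median depth was 1151194 counts in adult nociceptors, 972619 in mechanoreceptors and 1962651.5 in juvenile nociceptors. Mitochondrial transcripts took 0.358% to 0.868% of the counts in batch 1 and 3.20% to 27.6% in batch 2. Protein-coding genes took 98.3% to 99.2% and 69.1% to 94.7% of the counts. The small RNA gene Gm23935 took 40.0% to 73.1% of the deposited TPM in batch 2 but 0.330% to 0.590% in batch 1. Markers of satellite glia, the cells that wrap these neurons, summed to a median of 2247 CPM in batch 1 and 158 CPM in batch 2.

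**Figure D1:**
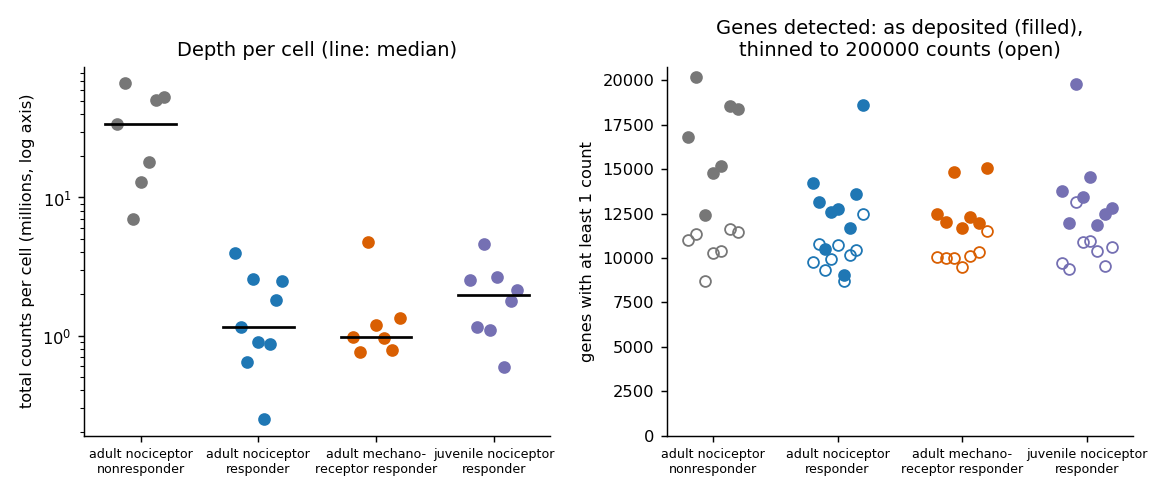
Total counts per cell on a log axis (left, line: median) and genes with at least 1 count per cell (right; filled points as deposited, open points after thinning to 200000 counts) for the 4 groups, 1 point per cell. The nonresponders lie between 7030197 and 67010440 counts and all other cells at or below 4764250 counts.

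The first comparison addressed how mechanoreceptors, the neurons of light touch, differ from nociceptors, the neurons of painful stimuli, among adult cells with a mechanically activated current. Transcripts of the pain neuron program were lower in mechanoreceptors. Ntrk1 (ENSMUSG00000028072), the receptor for nerve growth factor, was at 0.876 ± 0.553 CPM (SD, n = 3 pools) in mechanoreceptors and at 253 ± 185 CPM (n = 5) in nociceptors, a log2 fold change of -8.22 (SE 1.1, edgeR adjusted p = 0.0478). Cd9 (ENSMUSG00000030342), a tetraspanin of the cell membrane, was at 30.3 ± 6.79 CPM against 327 ± 196 CPM, a log2 fold change of -3.43 (SE 0.51, edgeR adjusted p = 0.0478). On the mm10 build Ntrk1 lies on chromosome 3 from 87778244 to 87795162 and Cd9 on chromosome 6 from 125460266 to 125494791. These were the 2 genes past the threshold among 14066 tested, both lower, with 0 genes higher.

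Nociceptor markers as a list fell in mechanoreceptors (camera adjusted p = 7.88e-10, and adjusted p = 0.0111 with an estimated correlation), with 16 of 17 members below 0 and a median log2 fold change of -1.48. That median was -2.95 without the mechanoreceptor pool of age 85 and -0.66 without the adult nociceptor pool of age 90, and the list passed camera each time. The labels state that the categories match marker expression, so that neither this list nor the other marker lists were independent evidence. Adjusted over the list alone, 4 members passed, all lower: Ntrk1, Calca (the precursor of the pain peptide CGRP), Prdm12 (a transcription factor of pain neurons) and Scn10a (the nociceptor sodium channel Nav1.8). Calca was at 15.9 ± 19.1 CPM against 951 ± 603 CPM (log2 fold change -5.86, SE 0.93), and Scn10a at 71.1 ± 118 CPM against 1497 ± 922 CPM (log2 fold change -4.38, SE 1.41). The latter was -8.93 without the mechanoreceptor pool of age 85, where mechanoreceptor 5 alone was at 773 CPM. Prdm12 had a log2 fold change of -3.77. Markers of peptidergic nociceptors, the neurons that release such peptides, also fell as a list, with 11 of 14 members below 0 and a median of -2.80 (camera adjusted p = 5.29e-08, and adjusted p = 0.00387 with an estimated correlation). Mechanoreceptor markers were higher as a list, with 17 of 22 members above 0 and a median of 0.90 (camera adjusted p = 0.00194), but not with an estimated correlation (adjusted p = 0.365), and 0 members passed. Their 2 members with the smallest p were Faim2, an inhibitor of cell death in neurons, at a log2 fold change of 1.50, and Nxph1, a neurexin ligand, which had 0 counts in the 3 mechanoreceptor pools and 4.30 ± 4.55 CPM in nociceptors.

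**Figure D2:**
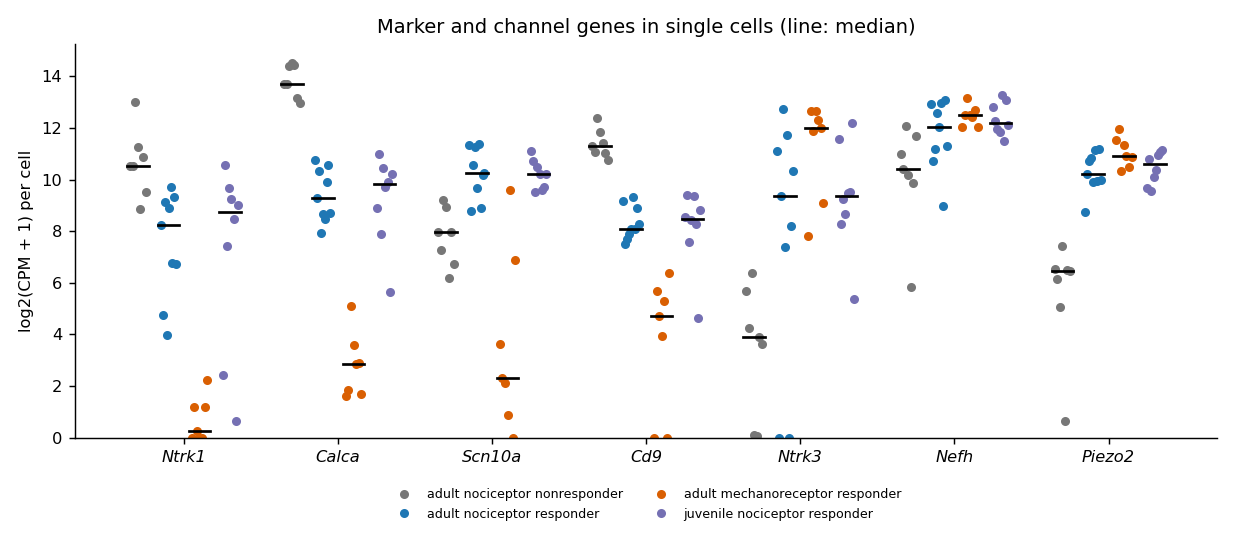
Expression of Ntrk1, Calca, Scn10a, Cd9, Ntrk3, Nefh and Piezo2 for the 4 groups on a log2(CPM + 1) axis, 1 point per cell (line: median). Over the age pools, which are not drawn, Ntrk1 was at a mean of 0.876 CPM in mechanoreceptors and 253 CPM in adult nociceptors.

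Ion channel genes moved in both directions, and neither the sodium, potassium nor calcium channel list passed camera. Adjusted over the list alone, 4 of 18 sodium channel genes passed: Scn7a, a sodium-sensing channel, was higher at 1621 ± 264 CPM against 816 ± 320 CPM (log2 fold change 0.99, SE 0.33), while Scn10a and the beta subunits Scn3b (log2 fold change -2.79) and Scn2b (log2 fold change -3.05) were lower. Among 30 calcium channel genes the 3 that passed were lower: Cacna1c (log2 fold change -2.77) and Cacna1e (log2 fold change -5.85), pore subunits of L- and R-type channels, and Cacna2d1 (log2 fold change -1.94), the gabapentin-binding subunit. Cacna1c was at -4.79 without the mechanoreceptor pool of age 85, and Cacna1e at -4.14 without the adult nociceptor pool of age 102, a single cell at 220 CPM where the others were at most at 32.6 CPM. Among 62 potassium and HCN channel genes, Kcna6, a subunit of delayed rectifier channels, was lower (log2 fold change -2.34, SE 0.51). Piezo2, the channel of rapidly adapting mechanical currents in touch neurons, was at 2145 ± 603 CPM in mechanoreceptors and 1170 ± 516 CPM in nociceptors (log2 fold change 0.87, SE 0.40), which did not pass. Of 36 mechanotransduction genes, 0 passed, adjusted over the list alone or over all genes. The 2 with the smallest p were Tmem63a, a channel opened by membrane stretch, with 2 against 136 counts (nociceptors over mechanoreceptors 50.3, counting interval 13.7 to 419), and the irritant receptor Trpa1, with 4 against 148 counts. Of these, 120 came from the adult nociceptor pool of age 90, a single cell. Without it the log2 fold change of Trpa1 went from -4.91 to -2.75. The mechanoreceptor transcripts Nefh, Ntrk3 and Ntrk2 had log2 fold changes of 0.76, 1.47 and 1.12 and did not pass, and Ntrk2 turned to -1.75 without the mechanoreceptor pool of age 85.

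Of the lists outside the neuron markers, 3 passed camera at the preset correlation and failed with an estimated one (adjusted p = 0.893 for each). Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, were higher, with 65 of 72 members above 0 and a median of 0.44 (camera adjusted p = 5.27e-06), among them Cyc1 (0.78) and Uqcrfs1 (0.74) of complex III. Genes of antigen presentation and the interferon response were lower, with 29 of 35 members below 0 and a median of -0.81 (camera adjusted p = 0.00612). In that list, Ddx58, a sensor of viral RNA, passed adjusted over the list alone (log2 fold change -2.65, SE 0.68). Cholesterol synthesis genes were lower, with 20 of 24 members below 0 and a median of -0.44 (camera adjusted p = 0.00892), among them the enzyme Lss (-1.22) and the sterol carrier Stard4 (-0.79). The interferon list no longer passed without the mechanoreceptor pool of age 85 (adjusted p = 0.269) or the adult nociceptor pool of age 92 (median -0.36, adjusted p = 0.088). Its median was -1.50 without the mechanoreceptor pool of age 115. The cholesterol list no longer passed without the mechanoreceptor pool of age 85 or 115 (adjusted p = 0.0574 and 0.425) or the adult nociceptor pool of age 89 (median -0.12, adjusted p = 0.586). Without the mechanoreceptor pool of age 89, a single cell, the oxidative phosphorylation median was 0.002 (adjusted p = 0.947), and with a covariate for glial markers that list and the interferon list no longer passed (adjusted p = 0.328 and 0.208).

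The calls of Ntrk1 and Cd9 lay close to the threshold, while their log2 fold changes without single pools stayed between -8.69 and -7.72 and between -3.62 and -3.04. Both ended when the 2 groups were fitted alone (0 genes called) and when any of the 3 mechanoreceptor pools was left out, whereas DESeq2 called 7 genes higher and 45 lower, and 6 genes were lower without the cells with over 18000 genes detected. Of the 56 splits of the 8 pools into 3 and 5, 26 gave at least 6 lists past camera. At an unadjusted p under 0.05 there were 594 genes (217 higher, 377 lower), where chance gives 703.3.

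The second comparison addressed maturation, as adult against juvenile nociceptors with a mechanically activated current. Genes of the stress and unfolded protein response were higher in adult cells as a list, with 28 of 34 members above 0 and a median log2 fold change of 0.34 (camera adjusted p = 2.78e-05, and adjusted p = 0.992 with an estimated correlation). Its members, of which 0 passed, included Dnajb9, a chaperone of the endoplasmic reticulum, at 75.5 ± 57.7 CPM (n = 5 pools) against 31.7 ± 12.5 CPM (n = 4), and Hmox1, the inducible heme oxygenase, at 59.1 ± 66.3 CPM against 16.0 ± 11.8 CPM. Immediate early genes, which neurons switch on within minutes of activity, were higher as a list, with 17 of 25 members above 0 and a median of 0.60 (camera adjusted p = 0.00149, and adjusted p = 0.992 with an estimated correlation). Their 2 members with the smallest p were Fosl1, an AP-1 transcription factor, at 34.5 ± 24.6 CPM against 12.6 ± 7.20 CPM, and Arc, a regulator of synapses, at 29.9 ± 45.1 CPM against 5.69 ± 2.32 CPM. Injury and regeneration genes were higher as a list, with 20 of 27 members above 0 and a median of 0.32 (camera adjusted p = 0.0161, and adjusted p = 0.992 with an estimated correlation). Gadd45a had a log2 fold change of 1.53 and Nfil3 of 1.66. Antigen presentation and interferon genes were higher as a list, with 25 of 35 members above 0 and a median of 0.33 (camera adjusted p = 0.0387, and adjusted p = 0.992 with an estimated correlation). Ifih1 had a log2 fold change of 2.03 and Stat2 of 1.17. Of the members of these 4 lists 0 passed, adjusted over the list alone or over all genes.

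No gene was past the threshold among 14066 tested (edgeR, 0 higher and 0 lower). At an unadjusted p under 0.05 there were 186 genes (95 higher, 91 lower), where chance gives 703.3, DESeq2 called 1 gene higher and limma-voom on cells called 0. Piezo2 was at 1170 ± 516 CPM in adult and 1450 ± 541 CPM in juvenile nociceptors (log2 fold change -0.31, SE 0.37). Ntrk1 (-0.71), Nefh (-0.50), Scn10a (0.30), Ntrk2 (1.61) and Ntrk3 (0.39) did not pass either, and the last 4 had an SE of 0.48, 1.04, 1.72 and 1.41. The mechanotransduction list had 17 members above 0 and 19 below (camera adjusted p = 0.972), with Asic1, an acid-sensing channel, at a log2 fold change of -1.69 (-0.74 without the juvenile pool of age 26, a single cell) and Rapgef3, a cAMP-regulated exchange factor, at 2.64. In the potassium channel list (camera adjusted p = 0.969) the 2 members with the smallest p were Kcnh5 (-1.64) and Kcnd2 (3.07). The list of growth genes of juvenile tissue had 15 members above 0 and 17 below (camera adjusted p = 0.969), with the growth factor adaptor Grb10 at 0.66 and the actin-binding protein Dbn1 at -0.43.

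Without the adult nociceptor pool of age 89, a single cell, the stress, immediate early and injury lists no longer passed (adjusted p = 0.0754, 0.314 and 0.125), and 1 list passed in all. Without the juvenile pool of age 28 the immediate early list no longer passed (adjusted p = 0.162), and the interferon list was lost without the adult pool of age 92, a single cell (median 0.024, adjusted p = 0.725). The injury list was also lost without the adult pool of age 92, the juvenile pool of age 27 or 28 or the mechanoreceptor pool of age 115 (adjusted p = 0.172, 0.244, 0.162 and 0.0516), with a median of 0.053 without the juvenile pool of age 27. The interferon list was also lost without any 1 of the mechanoreceptor pools or the juvenile pool of age 26, 27 or 28. Without the adult pool of age 89 the log2 fold changes of Arc, Hmox1, Dnajb9 and Nfil3 were 0.94, 0.96, 0.68 and 0.33, and without that of age 92 those of Ifih1 and Stat2 were 0.52 and 0.53. Of 100 splits of the 9 pools into 5 and 4, 69 gave at least 4 lists past camera.

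The third comparison set adult nociceptors with a mechanically activated current against those without. Responders and nonresponders were sequenced in different batches, and no batch held both groups, so that group and batch cannot be told apart in any value that follows. Piezo2 (ENSMUSG00000041482, chromosome 18 from 63010213 to 63387183 on mm10) was at 1220 ± 543 CPM (n = 5 pools) in responders and 70.0 ± 16.4 CPM (n = 5) in nonresponders, a log2 fold change of 4.12 (SE 0.39, edgeR adjusted p = 9.25e-06). Relative to all genes, calcium channel genes lay higher in responders and glycolysis genes lay lower. These were the 2 lists whose camera calls held with an estimated correlation (adjusted p = 0.0490 for each). Fold changes in this comparison also rose with exon length, and for neither list is a value with that trend removed given. Of 12421 genes, 1926 were higher and 2792 lower in responders, a share of 40.8% higher. That share was 51.6% with median-of-ratios size factors (2312 higher, 2169 lower), 50.7% with DESeq2 (2828 higher, 2755 lower) and 5.31% on the log2(TPM+1) scale (380 higher, 6774 lower). The median log2 fold change of all genes was -0.35, against -0.06 with median-of-ratios size factors and -1.55 on the log2(TPM+1) scale. Gm23935 took 40.0% to 73.1% of the TPM in batch 2 and 0.330% to 0.590% in batch 1. TPM columns share a single total, so that this share lowers all other genes of responders on that scale. Signs on the log2(TPM+1) scale are therefore not comparable with those on counts.

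The higher genes with the smallest adjusted p were Eef1a2, the elongation factor of mature neurons, at 1366 ± 197 CPM against 5.53 ± 3.55 CPM (log2 fold change 7.98, SE 0.46), the kinase Mink1 (6.21), the transcription cofactor Tcf20 (6.00), Prrc2a (5.66) and Scaf1 (5.20). The lower ones were Pebp1, an inhibitor of Raf kinase, at 13.6 ± 1.68 CPM against 139 ± 22.2 CPM (log2 fold change -3.36, SE 0.28), Ndufa1 of respiratory complex I (-3.14), Cyc1 of complex III (-3.02), the iron-sulfur assembly factor Ciapin1 (-2.93) and the proteasome subunit Psma2 (-2.81).

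Oxidative phosphorylation genes encoded in the nucleus were lower in responders, with 69 of 72 members past the threshold and a median log2 fold change of -2.36 (camera adjusted p = 1.02e-25, and adjusted p = 0.352 with an estimated correlation), for example Atp5g3 of ATP synthase at 66.7 ± 16.5 CPM against 484 ± 122 CPM. With each pool's trend with exon length removed the median was -1.11 and 41 members were lower. Genes encoded by the mitochondrial genome were higher, with 7 of 9 past the threshold and a median of 2.55 (camera adjusted p = 1.03e-06, and adjusted p = 0.352 with an estimated correlation). The ribosomal RNA mt-Rnr1 was at 25597 ± 23691 CPM against 147 ± 66.0 CPM, and mt-Nd5 at 2961 ± 771 CPM against 320 ± 101 CPM. The gene mt-Nd6 (3.10), from 13552 to 14070, overlaps the end of mt-Nd5, from 11742 to 13565, on the other strand. The 2 genes cannot be told apart within that overlap. Most of mt-Nd6 lies outside it, but there too the reads do not show which strand they came from. The level of mt-Nd6 is therefore uncertain. Glycolysis genes fell, with 16 of 24 members lower and a median of -1.76 (camera adjusted p = 0.00114, and adjusted p = 0.0490 with an estimated correlation), among them Eno1 (-2.77), Ldha (-2.82), Gapdh (-4.07) and the mitophagy receptor Bnip3 (-2.51). Many of these metabolic genes have near-identical pseudogenes with which reads of 50 bases can be shared, so that their levels are uncertain.

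Calcium channel genes lay higher than other genes as a list, with 11 of 24 members higher, 1 lower and 12 not past the threshold, and a median of 1.34, which was 2.49 without the nonresponder pool of age 89 and -0.58 on the log2(TPM+1) scale (camera adjusted p = 7.80e-04, and adjusted p = 0.0490 with an estimated correlation). Cacna1a and Cacna1b, pore subunits of the P/Q- and N-type channels of nerve terminals, had log2 fold changes of 5.21 and 4.31, Cacna1c had 4.11, and the ryanodine receptor Ryr2, which releases calcium from internal stores, had 4.80 (SE 0.68). Sodium channel genes had 7 of 16 members higher and 1 lower and a median of 1.69, which was -0.27 on the log2(TPM+1) scale (camera adjusted p = 0.0102, and adjusted p = 0.413 with an estimated correlation), among them Scn7a (2.88), Scn11a (3.21), Nalcn (2.31) and Scn9a, the pain channel Nav1.7 (1.43), which reversed to -0.27 on the log2(TPM+1) scale and to -0.35 with each pool's trend with exon length removed. Potassium and HCN channel genes had 14 of 55 members higher and 3 lower and a median of 0.82, which was -0.44 on the log2(TPM+1) scale (camera adjusted p = 0.0102, and adjusted p = 0.501 with an estimated correlation), among them Hcn2, a pacemaker channel of pain neurons, at 142 ± 50.1 CPM against 1.93 ± 0.753 CPM, Kcnab2 (3.56), Kcnb1 (3.01) and Kcnq2 (3.01). Synaptic transmission genes had 14 of 51 members higher and 5 lower and a median of 0.42, which was -1.34 on the log2(TPM+1) scale (camera adjusted p = 0.0246, and adjusted p = 0.352 with an estimated correlation). This list no longer passed without the nonresponder pool of age 84 or 93 (adjusted p = 0.0829 and 0.0513) or without the cells with over 18000 genes (adjusted p = 0.104). Those cells were adult nociceptor 9 and nonresponders 2, 6 and 7, which had 67010440, 50639612 and 53268958 counts. Their removal took out the nonresponder pools of ages 84 and 101 and the responder pool of age 90. The axon cytoskeleton list passed camera upwards (adjusted p = 0.00301, and adjusted p = 0.352 with an estimated correlation) with 13 members higher, 10 lower and a median of 0.03, which was -1.68 on the log2(TPM+1) scale. Its higher members included the large linker and motor proteins Dst (4.76), Dync1h1 (4.86), Sptbn1 (3.90) and Sptan1 (3.86).

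Relative to the median of all genes, the calcium, sodium, potassium and synaptic lists lay 1.69, 2.04, 1.16 and 0.76 higher, and 0.97, 1.28, 1.11 and 0.20 higher on the log2(TPM+1) scale. The axon cytoskeleton list turned from 0.37 to -0.13. Oxidative phosphorylation and glycolysis lay at -2.02 and -1.41 from that median, and at -2.58 and -1.62 on the log2(TPM+1) scale. Mitochondrially encoded genes lay 2.90 and 2.28 above it. Scn9a, whose sign turned on the log2(TPM+1) scale, also lay above that median, which was -1.55 there.

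Mechanotransduction genes had 9 of 33 members higher and 6 lower, and the list did not pass camera (adjusted p = 0.118). Beside Piezo2 its members with the smallest p were the clathrin heavy chain Cltc (2.26), the calcium pump Atp2a2 (2.03) and talin, Tln1 (2.51). Ntrk1 was lower at 262 ± 195 CPM against 3098 ± 4090 CPM (log2 fold change -3.57, SE 0.93, edgeR adjusted p = 0.0101), and at -2.32 without the nonresponder pool of age 90, a single cell at 10383 CPM (edgeR adjusted p = 0.0188). Ntrk3 (5.60, SE 1.74, edgeR adjusted p = 0.0256) and Scn10a (2.35, SE 0.58, edgeR adjusted p = 0.00631) were higher. Nefh (0.88) and Ntrk2 (1.48) did not pass, and both turned below 0 on the log2(TPM+1) scale (-0.66 and -0.13). The median of all genes was -1.55 on that scale, and both genes lay above it. Ntrk3 lost its call without the nonresponder pool of age 84, 89 or 101 (edgeR adjusted p = 0.0625, 0.0640 and 0.0651). Its log2 fold change without single pools stayed between 5.11 and 6.82. Ntrk3 and Scn10a lost their calls without the cells with over 18000 genes detected (edgeR adjusted p = 0.218 and 0.0517) and with the length trend removed (edgeR adjusted p = 0.310 and 0.0938), and Ntrk1 lost its call with the length trend removed (edgeR adjusted p = 0.0641). The removal of cells with over 18000 genes left out the nonresponder pools of ages 84 and 101, so that fewer replicates remained.

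Fold changes in this comparison rose with exon length (Spearman 0.53 across 12412 genes, which are not independent replicates). Among the tenth of genes with the shortest exons, with a median of 1427.5 bases, 4.19% were higher and 47.8% lower in responders, and among those with the longest, with a median of 12896.5 bases, 46.2% were higher and 2.90% lower. With each pool's trend with exon length removed, Piezo2, whose exons span 17162 bases, had a log2 fold change of 1.87 (edgeR adjusted p = 8.04e-04), 1245 genes were higher and 2128 lower, and 54.9% of the calls kept their direction and side of the threshold. Without the cells with over 18000 genes detected, nonresponders 2, 6 and 7 among them, 1340 genes were higher and 1649 lower. Of 100 splits of the 10 pools, 35 gave at least 8 lists past camera.

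**Figure D3:**
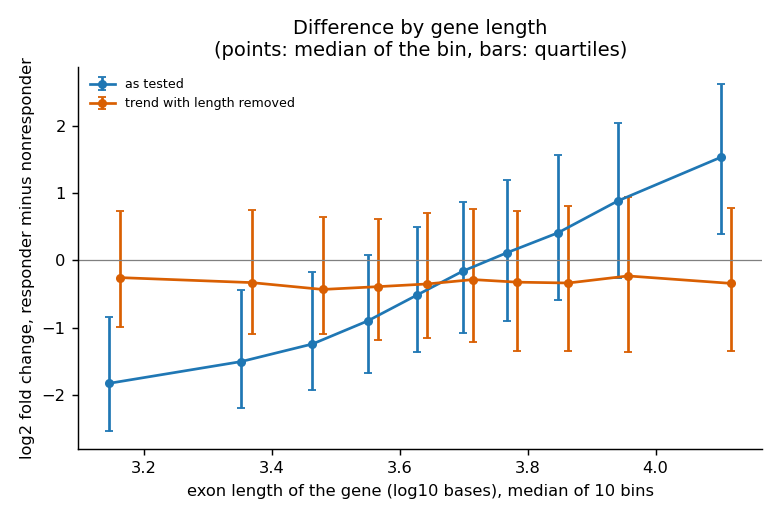
Median log2 fold change of responder against nonresponder nociceptors with its quartiles (bars) in 10 bins of exon length on a log axis, before and after each pool's trend with exon length was removed, drawn slightly apart sideways for display. Before removal the medians run from -1.83 in the bin of shortest exons to 1.53 in the bin of longest exons, and after removal they lie between -0.43 and -0.23.

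The fourth comparison concerned the currents themselves. Mechanoreceptors had a geometric mean of 3.48 nA over 3 pools (SD 0.37 on the log10 scale) and adult nociceptors of 0.701 nA over 5 pools (SD 0.39), a 4.97-fold difference that missed the threshold (exact permutation test, two-sided, p = 0.0536, where 0.0179 is the smallest p possible). On the nA scale the difference between the pool means was 7.82 nA (exact permutation test, two-sided, p = 0.0179), and without mechanoreceptor 2, a cell at 36.5 nA, it was 2.06 nA (exact permutation test, two-sided, p = 0.0179). On the log10 scale it was 0.49 without that cell (exact permutation test, two-sided, p = 0.107). Juvenile nociceptors had 1.03 nA over 4 pools (SD 0.12), against which adult nociceptors did not differ (exact permutation test, two-sided, p = 0.484). Across the 9 nociceptor pools of batch 2, current and Piezo2 had a Pearson r of 0.41 (exact permutation p = 0.259, adjusted p = 0.719) and a Spearman rho of 0.58 (exact permutation p = 0.108, adjusted p = 0.957), and r was 0.27 without the 2 pools farthest from the median. Of the 36 mechanotransduction genes tested in this family, 0 passed. The smallest p belonged to Smpd3, a sphingomyelinase (r = 0.74, exact permutation p = 0.0181, adjusted p = 0.474), a gene outside the naming rule that was chosen after its values were seen. Without the adult pool of age 89, the ubiquitin ligase gene Nedd4l passed (r = 0.93, exact permutation test, adjusted p = 0.00357), likewise chosen afterwards. Without the adult pool of age 92, r for Piezo2 was 0.77. No correlation was computed within the 5 adult or the 4 juvenile pools alone.

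**Figure D4:**
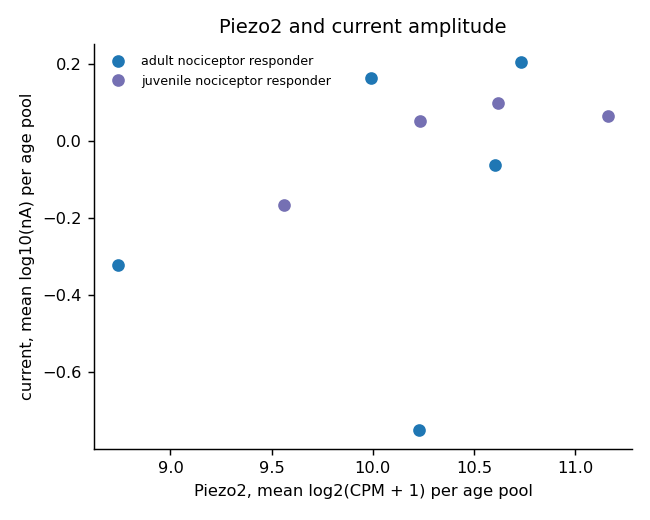
Mean log10 current in nA against mean Piezo2 expression in log2(CPM + 1) for the 9 age pools of nociceptors with a current, 5 adult and 4 juvenile. The adult pool of age 92 lies lowest, at -0.75 on the log10 scale.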

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

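In this part, the removal of the exon length trend, the thinning to equal depth and the tests on depth and on RNA from other cells in the libraries with many genes, and on the single library behind the stress genes, were chosen only after the result was seen. A value is given here when its gap to the nearest other value of its group took up more of the group's range than Dixon's critical value allows. Chance flags about 1 in 20 groups of independent, normally distributed values, which would give 9.1 of 182 groups, and 36 had such a value. The groups here shared cells and pools, and their values were not checked for a normal distribution. The excess over 9.1 is therefore no test.

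Responder and nonresponder nociceptors differed in 4718 genes, and oxidative phosphorylation genes were lower in responders. With each pool's trend with exon length removed 54.9% of the calls kept their direction and side of the threshold, and with every pool thinned to 637157 counts 72.7% did, which argues against gene length or depth as the whole cause. For oxidative phosphorylation genes, whose median exon length was 1778.5 bases against 4664 for all genes, the median went from -2.36 to -1.11, so that gene length may account for over 50% of it. After that removal 41 of 72 members were still lower (camera adjusted p = 1.27e-08, and adjusted p = 0.371 with an estimated correlation). Piezo2, whose exons span 17162 bases, went from a log2 fold change of 4.12 to 1.87, still past the threshold (edgeR adjusted p = 8.04e-04). Gene length may therefore account for over 50% of the Piezo2 difference as well. The sequencing batch cannot be told apart from the current, because 0 batches held both groups, and a biological difference between cells with and without a current also stays open, untested.

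Of the 24 libraries of batch 2, adult nociceptor 9 (age 90) and juvenile nociceptor 3 (age 26) had 18589 and 19780 genes detected. After thinning to 200000 counts they still had 12473 and 13172 genes, against at most 11527 in the others, which argues against depth. RNA from other cells is a candidate explanation, since satellite glia markers summed to 1283 and 2280 CPM against at most 757 in the other libraries, and fibroblast markers to 1023 and 1270 CPM against at most 662. Reads from the other libraries of the batch stay open, since 8 and 92 genes had more counts there than in the other 23 libraries together, which lies between what that source and its absence would give. Apoe, an abundant satellite glia transcript, had 1094 and 4904 counts there, against 7468 and 3658 in the other 23 libraries together, and no biological explanation was tested.

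Stress and immediate early genes were higher as lists in adult than in juvenile nociceptors at the preset correlation, but neither list passed with an estimated correlation (adjusted p = 0.992 for each), and 0 lists passed fry. In adult nociceptor 1, alone at age 89, Hmox1 (174 CPM), Dnajb9 (177 CPM), Arc (109 CPM) and Nfil3 (92.6 CPM) lay far above the other adult pools. Without this cell the lists had medians of 0.20 and 0.16 and a camera adjusted p of 0.0754 and 0.314, so that a single library may carry both calls. A difference with age stays open, untested beyond this comparison.

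Other splits of the pools into groups of the same sizes were compared with the real ones. For the 2 genes of the mechanoreceptor comparison, 1 of 56 splits, the real one, called as many, and the highest other count was 1. The margin is 1 gene, the categories match marker genes such as Ntrk1 per the labels, and 0 genes were called with the 2 groups fitted alone, so that this split count is no independent evidence of the calls. It cannot be excluded for its 6 lists, since 26 of the 56 splits gave as many and the highest other gave 11. Between adult and juvenile nociceptors 0 genes were called, so that 100 of 100 splits gave as many by construction (highest other 8), which says nothing about chance. It cannot be excluded for the 4 lists, since 69 of 100 splits gave as many and the highest other gave 15. Between responders and nonresponders 1 of 100 splits, the real one, gave 4718 genes, and the highest other gave 61. The real split is also the split by sequencing batch, and every other split mixes the batches. The count therefore shows only that the calls follow this shared division, not whether current or batch lies behind them. Chance cannot be excluded for the 8 lists, since 35 of 100 splits gave as many and the highest other gave 16.

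The remaining values that stood apart within their group have no explanation tested. Mitochondrial transcripts took 20.3% of the counts in adult nociceptor 9 and 27.6% in juvenile nociceptor 3. In the adult nociceptor pool of age 90, which is adult nociceptor 9 alone, mt-Rnr1 was at 66496 CPM, mt-Rnr2 at 124643 CPM and mt-Nd6 at 1814 CPM, and Trpa1 was at 48.3 CPM. Mechanoreceptor 3 had 4764250 counts, mechanoreceptor 2 a current of 36.5 nA and juvenile nociceptor 7 a current of 6.40 nA. Mechanoreceptor 7 had 11527 genes after thinning and fibroblast markers at 404 CPM. Among adult nociceptors, Cacna1e was at 220 CPM at age 102, Ifih1 at 57.6 CPM and Tln1 at 1267 CPM at age 92, and Kcnh5 at 25.9 CPM at age 115, while Cox6b1 was low at 27.4 CPM at age 102. Ntrk2 was at 122 CPM in the juvenile pool of age 26. The nonresponder pool of age 90, a single cell, stood apart with Ntrk1 at 10383 CPM, Scn10a at 751 CPM, Scn7a at 263 CPM, Kcnab2 at 169 CPM, Kcnb1 at 116 CPM, Ntrk3 at 106 CPM, Kcnq2 at 76.5 CPM, Nalcn at 46.2 CPM, Ryr2 at 21.1 CPM and Eef1a2 at 11.8 CPM, all high, and Piezo2 low at 41.6 CPM.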

How the results depend on the processing

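Removing cells with over 18000 genes detected or with the highest current, the exon length trend and thinning were chosen after seeing the data. In simulated data with the same 3 to 5 pools per group 0% of genes raised 2-fold were found in each comparison, and 50.0%, 58.8% and 61.8% of those raised 8-fold. The part played by depth was not simulated. The filter on cells under 100000 counts or 2000 genes removed 0 cells and says nothing. Responders and nonresponders were fitted alone throughout, so no such alternative existed for them. Across 21 kinds of alternative, named genes kept direction and side of the threshold in 638, 553 and 1206 cases in the mechanoreceptor, age and response comparisons, lost a call in 32, 0 and 38, gained one in 32, 0 and 0 and reversed in 1, 8 and 12. The 32 lost calls were all of Cd9 and Ntrk1, the only genes called in mechanoreceptors. With age 0 genes were called, so that no call could be lost. Most kept cases in mechanoreceptors, and all with age, were of genes not called in the main fit. Lists were tested with library size, a glial covariate, fry, an estimated correlation, without single pools and without the cells with over 18000 genes (oxidative phosphorylation in responders also without the length trend), and kept their camera direction and side of the threshold in 86, 41 and 111 cases and lost the call in 16, 27 and 9. On log2(TPM+1), where only medians were compared, those of the calcium, sodium, potassium, synaptic and axon cytoskeleton lists turned below 0 in responders (-0.58, -0.27, -0.44, -1.34 and -1.68), and the axon median was also -0.024 without the nonresponder pool of age 89. The median of all genes was -1.55 on log2(TPM+1), and of these lists the axon cytoskeleton list alone lay below it. The share of Gm23935 in the TPM of batch 2 lowers all other genes of responders on that scale. Where no cause is named, the cause was not tested.

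Between mechanoreceptors and nociceptors, where 2 genes were lower, 1 was lower with median-of-ratios factors and with library size alone, 9 with limma on log2(CPM+1), 6 with consecutive ages merged, 6 with log2(TPM+0.1), 6 without the cells with over 18000 genes, and 0 when the 2 groups were fitted alone, which left fewer pools. DESeq2 called 7 higher and 45 lower, limma-voom on cells 1 and 5, and log2(TPM+1) 1 and 2, and 0 of the 2 genes were among the calls of these last 2 alternatives. Leaving out single pools gave 0 to 4 lower and 0 higher genes and 4 to 9 lists, and Ntrk2 turned to -1.75 without the mechanoreceptor pool of age 85 (range up to 2.54). The calls of Cd9 and Ntrk1 ended without any 1 of the mechanoreceptor pools, the adult nociceptor pools of ages 102 and 115 or the juvenile pools of ages 27, 28 and 31 (adjusted p up to 0.637), and that of Ntrk1 also without the adult pool of age 89, while the log2 fold changes stayed between -3.62 and -3.04 and between -8.69 and -7.72. Of 6 lists, 2 passed camera with an estimated correlation and 2 passed fry.

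Between adult and juvenile nociceptors DESeq2 called 1 gene higher. Ntrk3 reversed with limma on log2(CPM+1) (-0.75) and limma-voom (-1.67), Ntrk1 with limma-voom (0.35) and Arc with log2(TPM+0.1) (-0.044). Without the adult pool of age 115 Ntrk3 was at -0.081 (range to 1.80), and without that of age 89 Scn10a was at -0.064 (range to 0.57). Of 4 lists, 0 passed camera with an estimated correlation and 0 passed fry. Leaving out single pools gave 1 to 11 lists and 0 genes.

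Between responders and nonresponders, with 1926 genes higher and 2792 lower, log2(TPM+1) gave 380 and 6774, log2(TPM+0.1) 348 and 6515, and log2(TPM+1) with no filter 348 and 6758. On these 3 scales Scn9a reversed to -0.27, -0.29 and -0.27, Nefh to -0.66, -0.66 and -0.66, and Ntrk2 to -0.13, -0.45 and -0.13. The median of all genes was -1.55, -2.23 and -0.75 on these scales, and each of these genes lay above it. On all 3 scales, the share of Gm23935 in the TPM of batch 2 lowers all other genes of responders. Limma-voom put Ntrk2 at -0.93. With the length trend removed 1245 genes were higher, Scn9a was at -0.35 and Ntrk2 at -0.85. Without the cells with over 18000 genes 1649 were lower, from fewer cells, since nonresponders 2, 6 and 7 and adult nociceptor 9 were left out. Of 8 lists, 2 passed camera with an estimated correlation, while 11 of the 26 lists passed fry, these 8 among them. Leaving out single pools gave 1623 to 2104 higher and 2301 to 3008 lower genes and 7 to 10 lists.

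With the labels' replicate numbers as a replicate block, 10 genes were higher and 4 lower in mechanoreceptors, 0 and 0 in adult against juvenile cells, with Ntrk2 at -0.11 and Ntrk3 at -0.0055, and 2908 and 3749 in responders. Cells of the same number were correlated at a median of -0.12, -0.14 and 0.02 between groups, and 1 of 7, 1 of 8 and 0 of 7 correlated best with their own number, so the numbers were read as names only.

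Mechanoreceptor and nociceptor currents differed by 7.82 on the nA scale, by 2.06 there without mechanoreceptor 2, at 36.5 nA, and by 0.50 to 0.87 on the log10 scale without single pools. Adult and juvenile currents differed by -0.26 to -0.02. Without single pools the correlation of current and Piezo2 ranged from 0.30 to 0.77, and 0 to 1 genes passed. It was 0.27 without the 2 pools farthest from the median, 0.18 on the log2(TPM+1) scale, 0.31 with ages merged and 0.53 with nA.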

Other observations

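All genes named in this part that fall outside the naming rule were chosen after their values were seen, and no further test was run. In mechanoreceptors against adult nociceptors, 3 neuronal genes that did not pass over all genes passed in their lists. Scg2, a granin of dense-core vesicles, was at 96.2 ± 14.9 CPM (n = 3 pools) against 1095 ± 783 CPM (n = 5), a log2 fold change of -3.51 (edgeR adjusted p = 0.0911 over all genes, and 0.00112 adjusted over the list alone). Chgb, another granin, was at 307 ± 113 CPM against 79.2 ± 31.8 CPM, a log2 fold change of 1.95 (edgeR adjusted p = 0.288 over all genes, and 0.00499 adjusted over the list alone). Gap43, a protein of growing axons, was at 41.3 ± 8.50 CPM against 381 ± 216 CPM, a log2 fold change of -3.21 (edgeR adjusted p = 0.235 over all genes, and 0.00270 adjusted over the injury list alone). Among 51 receptor genes, Ntrk1, the mu opioid receptor Oprm1 (-5.21) and the prostacyclin receptor Ptgir (-5.07) were lower, adjusted over the list alone, while the list did not pass camera (adjusted p = 0.442).

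In responder against nonresponder nociceptors, where the sequencing batch cannot be told apart from the group and 2792 of 12421 genes were lower, 7 of 13 peptidergic markers were lower and 0 higher, adjusted over the list alone. They included Calca at 972 ± 578 CPM (n = 5 pools) against 15721 ± 8782 CPM (n = 5), Calcb (-2.79), Tac1 (-5.53) and Gal (-5.76). The list did not pass camera (adjusted p = 0.11, and adjusted p = 0.599 with an estimated correlation). Of 28 injury and regeneration genes 9 were lower and 1 higher, adjusted over the list alone, among them Hspb1 (-3.20), Tnfrsf12a (-3.60) and Gap43 (-1.63), and that list did not pass either (adjusted p = 0.104). In the receptor list 5 of 49 genes were higher, among them Ngfr (4.03) and Gabbr2 (3.30), and 4 were lower, adjusted over the list alone (camera adjusted p = 0.681).

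Markers of other cell types did not pass camera in any comparison. Satellite glia, Schwann cell, fibroblast and endothelial lists had medians of -0.82, -0.32, -0.74 and 0.60 in mechanoreceptors against nociceptors, of -1.01, 0.05, -0.45 and -0.71 in adult against juvenile nociceptors, and of -2.18, -0.58, -1.11 and -1.15 in responders against nonresponders. The immune and red blood cell lists had under 5 tested members and were not tested. Markers of nonpeptidergic neurons and of low-threshold and cold-sensing neurons did not pass camera either (adjusted p = 0.887 and 0.461 in mechanoreceptors, 0.982 and 0.951 with age, and 0.800 and 0.700 with response).

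Single cells varied in their markers. Juvenile nociceptor 7 had Ntrk1 at 0.562 CPM, Ntrk3 at 4705 CPM, Cd9 at 23.6 CPM, Calca at 48.9 CPM and Scn10a at 829 CPM. Juvenile nociceptor 1 had Ntrk1 at 4.35 CPM. Adult nociceptor 4 had Ntrk1 at 14.9 CPM and Ntrk3 at 6866 CPM, and adult nociceptor 2 had Ntrk1 at 26.1 CPM. Mechanoreceptor 5 had Scn10a at 773 CPM and mechanoreceptor 4 had Trpv1 at 348 CPM.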
